A study of Mus musculus with 8 samples.

How the data were processed

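RNA from the gastrocnemius, a calf muscle made mostly of fast fibres, was profiled in 8 male wild-type mouse samples at day 4. Per the labels, 5 samples are controls given 10% glycerol and 3 are samples given cecal slurry, a suspension of gut contents used to produce polymicrobial sepsis. Per the labels' protocols, RNA was extracted on spin columns and 25 ng of total RNA entered a QuantSeq library kit, which reads a short stretch near the 3′ end of polyadenylated transcripts. Such libraries give about 1 read per captured transcript end, so counts were not divided by transcript length. Per the submitters' processing notes the genome build was GRCm39. The aligner, the counting tool, its strand setting and the annotation release were not given in the sources used here.

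The authors deposited raw read counts per gene, with 1 column per library and no pooling, and these whole-number counts were the only values used. The table held 25655 gene rows, of which 9287 had no read in any library. Every row carried a gene name, and 35 rows carried a number added to a repeated symbol. Of the identifiers, 25600 were found in the reference name table used here and 55 were not. That reference belongs to an earlier mouse build, so it served only to check names and no coordinates are given. Total counts per library ran from 3086277 to 4016329. At this depth 1 read corresponded to 0.315 CPM in an average control library and 0.235 in an average septic library. Counting intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

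Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter with a minimum count of 10 and a minimum total of 15, which left 9810 genes. Library sizes were scaled by trimmed means of M values (TMM), and the quasi-likelihood F test with robust dispersion estimation compared sepsis with control over all 8 libraries, with no covariate. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Log2 fold changes are sepsis minus control, and CPM, counts scaled to a common library size, were computed with the TMM-scaled library sizes. The SE given beside a log2 fold change is its absolute value divided by the square root of the F statistic. It is derived from the test and is not an output of edgeR. A gene with 1 to 3 reads in a group is given as a ratio of reads with its 95% counting interval. A gene with no read in a group is given as a lower bound, from a floor of 3 reads over that group.

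Before the data were examined, 50 gene lists with 1125 members were fixed, covering muscle atrophy, energy metabolism, contraction, inflammation, stress and growth, together with markers of other cell types. Of these members, 1119 matched a row. Aldoa and Ddit3, whose reads are spread over numbered rows, were among the 6 left out. Lists with at least 5 tested members, 47 in all, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera asks whether a list moves relative to all other genes. It was repeated with the correlation estimated from these libraries, and fry was run beside it, which tests only whether the genes of a list move, on balance, in a single direction and does not compare them with other genes. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. These counts are out of the members with enough reads to be tested, which in many lists are fewer than the members fixed.

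The genes named follow a rule fixed before the data were examined. It takes the 10 largest increases and the 10 largest decreases past the threshold, with an average log2 CPM of at least 3 and no overlap between the groups. It adds up to 3 members per list with the smallest p, members needed to say what the moving members of a list are, and 16 key genes. Predicted genes were passed over, which applied to 1 gene among the increases. The rule's top, list and key parts gave 162 genes, from which the text takes examples. Some members of the lists are not reported here by name. Named to say what moved in a list, and chosen after their values were seen, were Trim32, Cox8a, mt-Co1, Mrpl41, Rpl3l, Rpl10, Rpl23a, Slc2a1, Nmnat1, Nmnat3, Sirt5, Parp14, Sirt7, Perm1, Mief1, Nr3c1, G0s2, Retnlg, Col4a1, Col4a2, Hsd11b1, Kera, Smox, Sat1, Amd2, Tfrc, Igf1, Dbp, Myh2 and Cyp2e1, and the members of symbol families. Single values per library were compared by a two-sided exact permutation test over the 56 ways of splitting the libraries into 5 and 3, whose smallest possible p is 0.0179.

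The procedure was tested on simulated data. In 10 simulations of the sepsis against control comparison, 200 of 9810 genes were changed 1.5-fold, 2-fold or 4-fold. A further 30, raised by 0.6 on the log2 scale for the list tests, also counted as truly changed. Of the 200, edgeR recovered 15.2% of genes changed 1.5-fold, 54.5% of those changed 2-fold and 91.5% of those changed 4-fold. Of its calls, 8.5% were false, against the 5% expected. The shares recovered and the false share hold for the simulated mix of changed and unchanged genes. They do not carry over to the real counts. The alternatives tried were DESeq2 size factors, library totals without TMM, upper-quartile factors, TMM without mitochondrial and the 10 most abundant genes, no low-count filter, a stricter filter of 5 CPM in 3 libraries, the DESeq2 1.42.0 test, limma-voom, edgeR without robust estimation, a log2 fold change of at least 1, each library left out in turn, and the replicate number as a block. Reads of near-identical genes cannot be assigned with certainty near the 3′ end, which applies to Amd1 and Amd2, the haemoglobin genes, the H2 genes, Acot2, Ubb, and ribosomal protein genes with pseudogenes. Figures were drawn with matplotlib 3.10.9.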

Results

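Gene expression was measured in the gastrocnemius of male wild-type mice at day 4, in 5 control samples given 10% glycerol and 3 samples given cecal slurry to produce sepsis. The series title concerns β-nicotinamide mononucleotide, a precursor of the coenzyme NAD, but samples treated with it were not analysed here. The libraries held 3581128 ± 343461 counts in controls (mean ± SD, n = 5) and 3595872 ± 227155 in sepsis (n = 3), so depth did not differ by more than its spread. No pair of libraries within a group agreed within sampling noise, and septic libraries differed more from each other than controls did. The chi-square per degree of freedom was 2.16 to 7.63 between controls and 12.2 to 29.5 between septic libraries. EdgeR's test fits a common dispersion per gene to both groups, so it does not model this difference. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples. The composition of the libraries differed: reads from mitochondrially encoded genes made up 23.6% ± 1.89 of counts in controls and 14.5% ± 2.19 in sepsis, and the 10 most abundant genes made up 36.5% ± 0.351 and 23.7% ± 1.5. Each of these differences had p = 0.0179 in an exact permutation test, the smallest the design allows, and adjusted p = 0.0536 over 9 such comparisons. The first principal component held 70.1% of the variance and placed the controls between -40.3 and -34.6 and the septic libraries between 48.7 and 78.0.

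The comparison of sepsis with control asks which transcripts of the calf muscle differ at day 4 of sepsis. Lists of genes of protein breakdown and acute-phase signalling were higher in septic muscle, and lists of the respiratory chain, glycolysis, fast fibres, excitation-contraction coupling and extracellular matrix were lower. These are camera calls, and each was lost with an estimated correlation, at adjusted p = 0.306 or, for the matrix, 0.344. Fbxo32 and Trim63, which encode the muscle ubiquitin ligases atrogin-1 and MuRF1, rose 8.98-fold and 16.7-fold, with log2 fold changes of 3.17 (SE 0.19) and 4.06 (SE 0.34) over 5 controls and 3 septic libraries. All 32 proteasome subunit genes rose, with a median of 3.03-fold. Of 79 nuclear-encoded respiratory chain and ATP synthase genes tested, 73 fell, 1 rose and 5 did not pass, and calsequestrin-1 (Casq1), the calcium-binding protein of the calcium store in fast fibres, fell 21.2-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4943 of 9810 genes changed, 2475 higher and 2468 lower, of which 1157 and 1396 changed at least 2-fold. The groups did not overlap in 47.5% of the genes tested, against a chance share of 3.6%. Scaling decided the balance of directions: with library totals alone the median log2 fold change of all genes moved from 0.01 to 0.43, and the share of higher genes among those called moved from 50.1% to 75.4%.

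Among the 10 largest increases past the threshold were genes of secreted defence proteins and 2 metallothioneins. Lipocalin-2 (Lcn2, ENSMUSG00000026822), an iron-sequestering defence protein, had 2 reads over the 5 controls and 1026 over the 3 septic libraries, a ratio of 637 with a 95% counting interval of 176 to 5265. The calprotectin genes S100a8 and S100a9 had 3 and 2 control reads, with ratios of 340 (116 to 1651) and 318 (87.5 to 2631). Serum amyloid A3 (Saa3) rose from 1.18 ± 0.596 to 245 ± 60.5 CPM. The metallothioneins Mt2 and Mt1 rose from 33.2 ± 18.5 to 5296 ± 996 CPM and from 54.1 ± 25.4 to 4156 ± 505 CPM. The chemokine gene Cxcl13 had a ratio of 99.7 (33.7 to 487), and Doc2b, a regulator of vesicle fusion, and the serine protease inhibitor gene Serpina3n rose 92.5-fold and 79.5-fold. Itpkc, an inositol trisphosphate kinase gene, had 2 control reads, both in control 1, and a ratio of 175 (48.0 to 1452). Its call was lost without that library, where the remaining controls held no read and the fitted fold change is no measure of size; edgeR's Benjamini-Hochberg adjusted p was then 0.0753, against 1.72e-05 to 0.0753 over all alternatives.

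The largest decreases included genes of the muscle membrane and of tendon and cartilage matrix. Tmem233, a transmembrane protein gene, fell from 246 ± 30.7 to 1.54 ± 1.11 CPM. The water channel gene Aqp4 and the matrix gene Chad each had 1 read over the septic libraries, and their controls exceeded sepsis by ratios of 195 (34.7 to 7732) and 184 (32.6 to 7287). Lrrc38, which encodes a potassium channel subunit, fell 94.4-fold, and Cited4, a transcriptional coregulator gene, fell 70.4-fold. The myosin-binding protein gene Mybph, the cadherin gene Cdh4, the growth factor-binding protein gene Igfbp5, Nrep and the cartilage matrix gene Cilp2 fell between 38.8-fold and 55.0-fold. Igfbp5 was the most abundant of these and fell from 515 ± 68.9 to 11.8 ± 1.82 CPM.

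Genes of protein breakdown rose together. Besides Fbxo32 and Trim63, the atrophy list held Eif4ebp1, a repressor of translation initiation, with a log2 fold change of 3.76 (SE 0.12), and the ligase gene Fbxo31 with 2.40 (SE 0.11). Of its 24 members 14 rose and 4 fell, among them Trim32 at -1.26, and with library totals alone 16 were higher and 0 lower. With TMM scaling the number lower was 2 without control 3 or sepsis 1. The proteasome genes Psma7, Psmc4 and Psmd8 rose 5.63-fold, 4.28-fold and 3.62-fold. In the autophagy and lysosome list 20 of 31 members rose and 2 fell, and the lysosomal protease genes Ctsl and Ctsd rose 5.33-fold and 2.68-fold and the autophagy receptor gene Sqstm1 3.92-fold. The counts adjusted over the list alone were 14 and 4 for atrophy, 32 and 0 for the proteasome, and 21 and 2 for autophagy. Camera called the 3 lists higher, with adjusted p-values of 0.00228, 4.26e-17 and 3.20e-05. Each had an adjusted p = 0.306 with an estimated correlation.

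**Figure D1:**
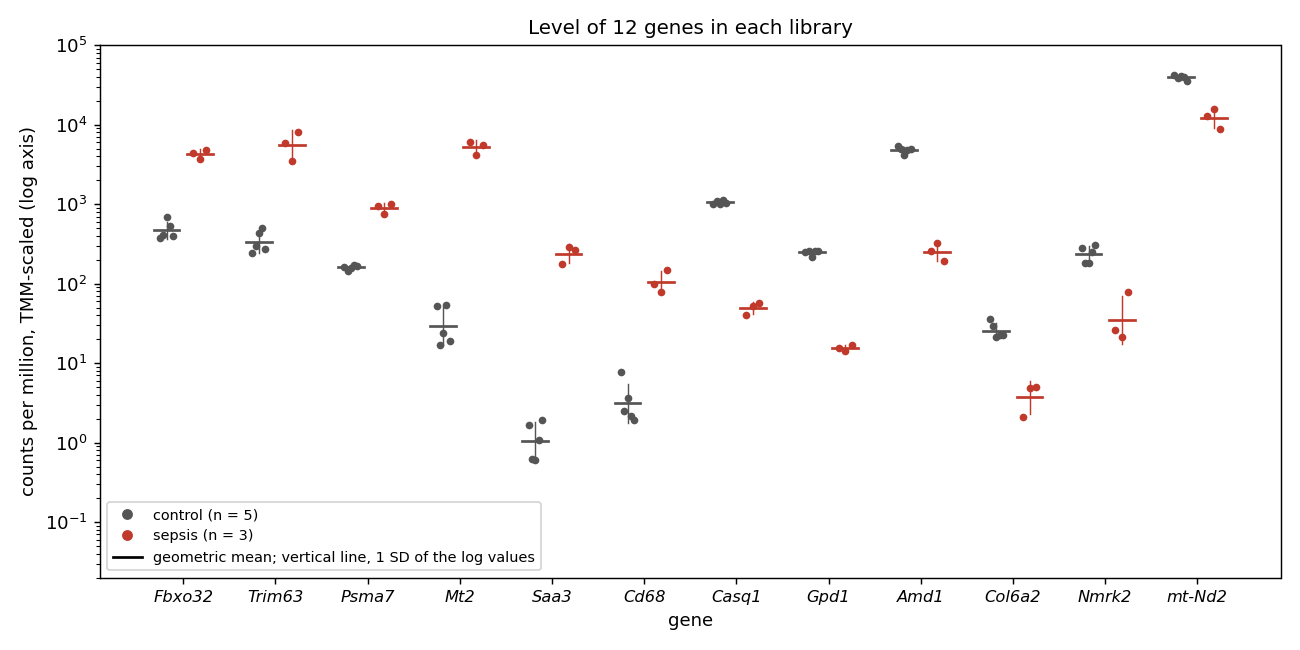
TMM-scaled CPM (log axis) of 12 genes in each of the 5 control (grey) and 3 septic (red) libraries; horizontal lines are geometric means and vertical lines span 1 SD of the log values either way. In these 12 genes every septic library lies beyond every control library, and Mt2 rises from 33.2 to 5296 CPM on average while Amd1 falls from 4835 to 258 CPM.

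Most respiratory chain genes fell in each list, with complexes II and III counted together. In complex I, 35 of 36 members fell, with Ndufb8 at -1.68 (SE 0.12), Ndufv3 at -1.52 (SE 0.10) and Ndufb10 at -1.50 (SE 0.11) on the log2 scale. In complexes II and III 11 of 13 members fell, and cytochrome c1 (Cyc1) fell 4.60-fold. In the list of complex IV and its electron donor cytochrome c 13 of 15 fell, including Cox7a1 and the cytochrome c gene Cycs, and Cox8a rose with 0.54, a call lost without sepsis 1. In ATP synthase 14 of 15 fell, and Atp5a1 fell 2.73-fold. Among the 13 mRNAs of the mitochondrial genome 12 fell, mt-Nd1 by 1.46 and mt-Nd2 by 1.66 on the log2 scale, while mt-Co1 had -0.09 (SE 0.14). In the TCA cycle 18 of 20 fell and 1 rose (0 without control 3 or sepsis 1), with Idh3a, Suclg1 and citrate synthase (Cs) falling 3.29-fold, 2.86-fold and 2.43-fold. The counts were the same adjusted over the list alone for these 6 lists, and camera called each lower, with adjusted p-values between 3.72e-13 and 6.92e-05. The adjusted p = 0.306 with an estimated correlation for each of them. With library totals alone the medians stayed negative but were smaller, at -0.74 for complex I and -0.27 for complex IV with cytochrome c. The members lower and higher were then 29 and 0 in complex I, 9 and 0 in complexes II and III, 9 and 2 in complex IV with cytochrome c, 11 and 1 in ATP synthase, 11 and 1 among the mitochondrial mRNAs, and 9 and 1 in the TCA list.

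Mitochondrial and cytosolic ribosomal protein genes went in opposite directions. Of 56 mitochondrial ribosomal protein genes 32 fell and 1, Mrpl41, rose, with Mrpl42 falling 3.18-fold. Their camera adjusted p was 3.20e-05, and adjusted p = 0.306 with an estimated correlation. With library totals alone the balance was 15 lower and 11 higher at a median of -0.08. With TMM scaling 3 were higher without control 4 and 2 without sepsis 2. All 53 genes of the cytosolic ribosomal protein list, which does not hold every such gene, rose by small amounts (52 without control 3 or sepsis 3), with a median of 0.64, and Rpl11 rose 2.07-fold. Outside the list Rpl3l, a muscle paralog of Rpl3, fell by 1.14 on the log2 scale, and Rpl10 and Rpl23a had 0.68 and 0.14 without passing. Their camera adjusted p was 6.53e-13, and adjusted p = 0.338 with an estimated correlation. Both lists had the same counts adjusted over the list alone.

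Glycolysis genes fell. Of 24 members 17 were lower past the threshold and 2 higher, with a median of -1.42. The glycerol phosphate dehydrogenase gene Gpd1 fell 16-fold, Pgm1, which links glycogen to glycolysis, 10.6-fold, and the lactate dehydrogenase gene Ldha 4.52-fold, while the glucose transporter gene Slc2a1 rose with 1.38. Camera's adjusted p was 4.53e-06, and adjusted p = 0.306 with an estimated correlation. Genes induced by fasting rose in 10 of 13 cases with a median of 1.67, among them the triglyceride lipase gene Pnpla2, up 4.34-fold, Slc25a34, up 5.51-fold, and Pdk4, which restrains pyruvate oxidation, up 6.28-fold. The call of Pdk4 was lost without sepsis 3, where its log2 fold change was 2.31 instead of 2.65 and edgeR's Benjamini-Hochberg adjusted p was 0.0511, the highest over its alternatives. The pyruvate dehydrogenase phosphatase gene Pdp1 fell 3.44-fold. This list had a camera adjusted p of 0.00582, and adjusted p = 0.306 with an estimated correlation. Fatty acid uptake and oxidation genes went both ways, with 6 higher, among them Acadl and Eci2, and 9 lower, among them Acot13, and with library totals alone the median of -0.04 became 0.37, with 13 higher and 4 lower. With TMM scaling and single libraries left out, this median lay between -0.12 without sepsis 1 and 0.08 without sepsis 2, and was -0.09 without control 1, -0.02 without control 3 and -0.10 without sepsis 3. That list was not called, with a camera adjusted p of 0.726. All 3 of these lists had the same counts adjusted over the list alone.

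Among genes of NAD metabolism 19 of the 33 listed had enough reads, of which 2 rose and 7 fell, with the same counts adjusted over the list alone. The nicotinamide riboside kinase gene Nmrk2, which makes nicotinamide mononucleotide in muscle, fell from 241 ± 58.8 to 41.6 ± 31.3 CPM, with a log2 fold change of -2.53 (SE 0.47). The poly(ADP-ribose) polymerase genes Parp1 and Parp3 fell 3.09-fold and 2.15-fold, the mitochondrial deacylase gene Sirt3 4.04-fold, and Nmnat1, Nmnat3 and Sirt5 also fell. Parp14 and Sirt7 rose, with 1.14 and 0.83. Nampt, the rate-limiting gene of NAD salvage, was at 83.1 ± 9.61 and 85.0 ± 28.7 CPM, with 0.03 (SE 0.20), and it passed the threshold only with library totals alone, at 0.43. Cd38 had 0.37 (SE 0.35). Sirt1 had 0.67 (SE 0.29) at a Benjamini-Hochberg adjusted p of 0.0707 in edgeR (0.00583 to 0.247 over its alternatives), and it passed with library totals alone at 0.00583, without control 2 at 0.0453 and without sepsis 2 at 0.0169, with log2 fold changes of 1.08, 0.82 and 0.92. Nnmt had too few reads to be tested, with 1.44 ± 1.03 and 1.55 ± 0.440 CPM. With library totals alone 7 members were higher and 4 lower. Camera did not call the list, at an adjusted p of 0.418, and its signs differed: the median was 0.03 (-0.03 with upper-quartile factors, -0.02 without control 2 or sepsis 2, 0.01 without control 3, 0.08 without sepsis 1 and 0.09 without control 1), while the mean was -0.32 and the test pointed down.

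Genes of mitochondrial biogenesis were not called as a list, with a camera adjusted p of 0.450. In it 7 of 24 members fell, including the nuclear receptor gene Esrra, its coactivator Ppargc1b and Perm1, with Esrra falling 3.38-fold and Ppargc1b 2.84-fold. Gabpa, a transcription factor gene, rose 1.95-fold and Mief1 rose as well. Ppargc1a had a log2 fold change of -0.63 (SE 0.49). The median of -0.19 became 0.23 with library totals alone, where 11 members were higher and 4 lower. With TMM scaling it was -0.10 without control 4 and -0.06 without sepsis 3, and 1 member was higher without control 1, 4 or 5 or sepsis 1. As counts adjusted over the list alone, 2 rose and 7 fell.

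Fast-fibre and excitation-contraction genes fell. Of 17 fast-fibre genes 16 fell, with a median of -1.36, and tropomyosin 1 (Tpm1) and the myosin light chain gene Mylpf fell 4.53-fold and 3.85-fold. Myh4, the myosin heavy chain of the fastest fibres, fell by 0.57 on the log2 scale, a call lost with library totals alone, where it had -0.16. Its share of adult myosin heavy chain reads was 94.5% ± 0.344 in controls and 95.6% ± 2.24 in sepsis, with p = 0.357 in an exact permutation test. Of 23 excitation-contraction genes 18 fell and 1 rose, with the sodium channel subunit gene Scn4b falling 11-fold and Sypl2, a triad membrane gene, 20.1-fold. Camera's adjusted p-values were 3.06e-07 and 5.72e-07, and each list had an adjusted p = 0.306 with an estimated correlation. These 2 lists had the same counts adjusted over the list alone.

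Structural and slow-fibre genes were mixed. Of 25 sarcomere genes 12 fell, such as Tmod1 and the creatine kinase gene Ckm, down 3.23-fold and 2.66-fold, and 5 rose, such as filamin C (Flnc), up 6.95-fold, against 9 and 9 with library totals alone. With TMM scaling the number higher was 9 without sepsis 3 and 3 without sepsis 1. Of 11 slow-fibre genes 4 fell, among them the light chain gene Myl3 and myoglobin (Mb), and 1 rose, and with library totals alone the median of -0.24 became 0.18, with 3 higher and 2 lower. With TMM scaling it was -0.08 without control 3, -0.46 without sepsis 1 and -0.12 without sepsis 2, and 2 genes were higher without sepsis 3 and 0 without control 2, control 3, sepsis 1 or sepsis 2. Myh7 had -0.06 (SE 0.28), which became 0.35 with library totals alone. Of 19 denervation and embryonic muscle genes 9 rose and 5 fell, or 10 and 3 with library totals alone. The receptor kinase gene Musk and Xirp1 rose 5.05-fold and 7.72-fold, and the adult acetylcholine receptor subunit gene Chrne fell 13-fold. Camera called none of these 3 lists, at adjusted p-values of 0.0744, 0.362 and 0.174. The sarcomere list did pass with library totals alone at 0.0377 and without sepsis 1 at 0.0104. Its camera alternatives with the preset correlation ranged from 0.0104 to 0.325. Adjusted over the list alone, 6 sarcomere genes rose and 12 fell, and the other counts were the same.

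Of 48 acute-phase and inflammatory signalling genes listed 22 had enough reads. Of these 18 rose past the threshold and none fell, with a median of 1.57. Lcn2 and Saa3, with few control reads, passed the expression filter only through the septic libraries. The adhesion molecule gene Icam1 rose 27.0-fold and the interleukin-6 receptor gene Il6ra 4.64-fold. Socs3, a feedback inhibitor of cytokine signalling, rose 2.41-fold, a call lost without sepsis 1, where the log2 fold change was 0.72 instead of 1.27, at an edgeR Benjamini-Hochberg adjusted p of 0.0764, the highest over its alternatives. Glucocorticoid-responsive genes rose in 14 of 20 cases and fell in 1, the receptor gene Nr3c1, and Tsc22d3 rose 2.58-fold. This list shares Mt1, Mt2 and other members with further lists. Camera's adjusted p-values were 3.41e-07 and 1.74e-05, and each list had an adjusted p = 0.306 with an estimated correlation. Neither count differed when adjusted over the list alone.

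Markers of leukocytes moved with these genes. Of 17 neutrophil markers 7 had enough reads, 6 of which rose and 1, G0s2, fell, though not without sepsis 3. The granule protein gene Ngp and Retnlg had no read in controls and were at least 29.4-fold and 27.3-fold higher. Lcn2, S100a8 and S100a9 had only 2 or 3 reads over the controls. These genes passed the expression filter through the septic libraries only, so they could only come out higher. The list's count and its camera call rest largely on them. The list's median was 7.32 as fitted and 4.88 with such genes at their bounds. Of 26 monocyte and macrophage markers 18 had enough reads, of which 12 rose, or 8 without sepsis 2. Among them Cd68 rose 29.3-fold, the integrin gene Itgam 7.06-fold and the scavenger receptor gene Cd163 3.85-fold. Of 7 genes of MHC class II and dendritic cells 5 fell, with H2-Aa, H2-Ab1 and Cd74 down 6.56-fold, 5.78-fold and 3.63-fold. Without control 1 or control 2, 5 of these genes had enough reads and 4 fell. Camera's adjusted p-values for these 3 lists were 0.000110, 0.000365 and 0.0163, and with an estimated correlation the adjusted p = 0.306, 0.431 and 0.306. Adjusted over the list alone, 13 macrophage markers rose and the other counts were the same. Summed haemoglobin transcripts were at 530 ± 435 CPM in controls and 59.0 ± 39.5 in sepsis. None of 21 T, NK and B cell markers had enough reads to be tested. Among class I antigen presentation genes 7 of 13 rose, with H2-K1 up 2.20-fold and H2-Q7 up 5.76-fold, and adjusted over the list alone 7 rose and 1 fell. Camera's adjusted p was 0.0293, and adjusted p = 0.499 with an estimated correlation. The call was also lost with library totals alone (0.0892), without sepsis 2 (0.0840) and without sepsis 3 (0.108). Over the camera alternatives with the preset correlation its adjusted p ranged from 0.00104 to 0.108.

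Interferon and complement genes were not called as lists, at camera adjusted p-values of 0.359 and 0.397. Of 38 interferon-stimulated genes listed 18 had enough reads. Of these 5 rose, among them Rsad2, and 1 fell, and adjusted over the list alone 4 rose and none fell. Without sepsis 1, 11 of 24 then tested were higher and the list was called at 0.000855 (up to 0.723 over its alternatives with the preset correlation). Without control 2 there were 3 higher, and without sepsis 3 there were 2, and 0 were lower without control 1, 2 or 4 or sepsis 1 or 3. Of 15 complement genes 6 rose, with C1qb and C4b up 3.39-fold and 2.75-fold, and 4 fell, with the complement inhibitor gene Cd55 down 4.80-fold. Adjusted over the list alone 8 rose and 4 fell, with library totals alone 9 were higher and 1 lower, and over all genes 3 rose without sepsis 2, 9 without control 1 and 4 without each other control. C1qa, C1qb and C1qc are also among the macrophage markers.

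Connective tissue genes fell. Of 28 extracellular matrix genes 21 fell and 2, the basement membrane collagens Col4a1 and Col4a2, rose, with a median of -1.52. Col6a2 fell 6.43-fold, fibrillin-1 (Fbn1), which stood apart at 68.6 CPM in control 1, 4.44-fold and the collagen hydroxylase gene P4ha1 2.80-fold. Markers of fibro-adipogenic progenitors and fibroblasts fell in 14 of 20 cases (9 lower and 3 higher, at a median of -0.61 instead of -1.04, with library totals alone), with Serpinf1 down 17.1-fold, while Apod and Hsd11b1 rose 4.11-fold and 9.91-fold. Of 8 tendon markers 7 fell, among them fibromodulin (Fmod), down 19.3-fold, and Tnmd, which had 2 septic reads and a ratio of control to sepsis of 45.5 (12.3 to 380). The tendon median was -3.63 as fitted and -3.36 with Kera, unread in sepsis and at least 13.2-fold lower, at its bound. Chad, Tnmd and Kera, with few or no septic reads, passed the expression filter through the controls only, so they could only come out lower. The list's count, median and camera call rest partly on them. Camera's adjusted p-values for the matrix, fibroblast and tendon lists were 1.61e-05, 0.00114 and 4.93e-05, and with an estimated correlation the adjusted p = 0.344, 0.306 and 0.306. Adjusted over the list alone, the counts of these 3 lists were the same.

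Genes of polyamine and amino acid metabolism fell in 12 of 22 cases and rose in 5, and adjusted over the list alone 13 fell and 5 rose. Amd1, whose enzyme makes the aminopropyl donor for spermidine, fell 18.8-fold from 4835 ± 461 CPM, and the polyamine oxidase gene Smox fell 21.8-fold, while Sat1, which acetylates polyamines for export, rose 4.03-fold. Amd1 may share reads with its near-identical copy Amd2, which also fell. Camera's adjusted p was 0.0270, and adjusted p = 0.306 with an estimated correlation. Without sepsis 2 the camera value was 0.0616, the highest over its alternatives with the preset correlation. With library totals alone 8 members were higher and 8 lower. With TMM scaling 3 were higher without control 1, 3 or 5.

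**Figure D2:**
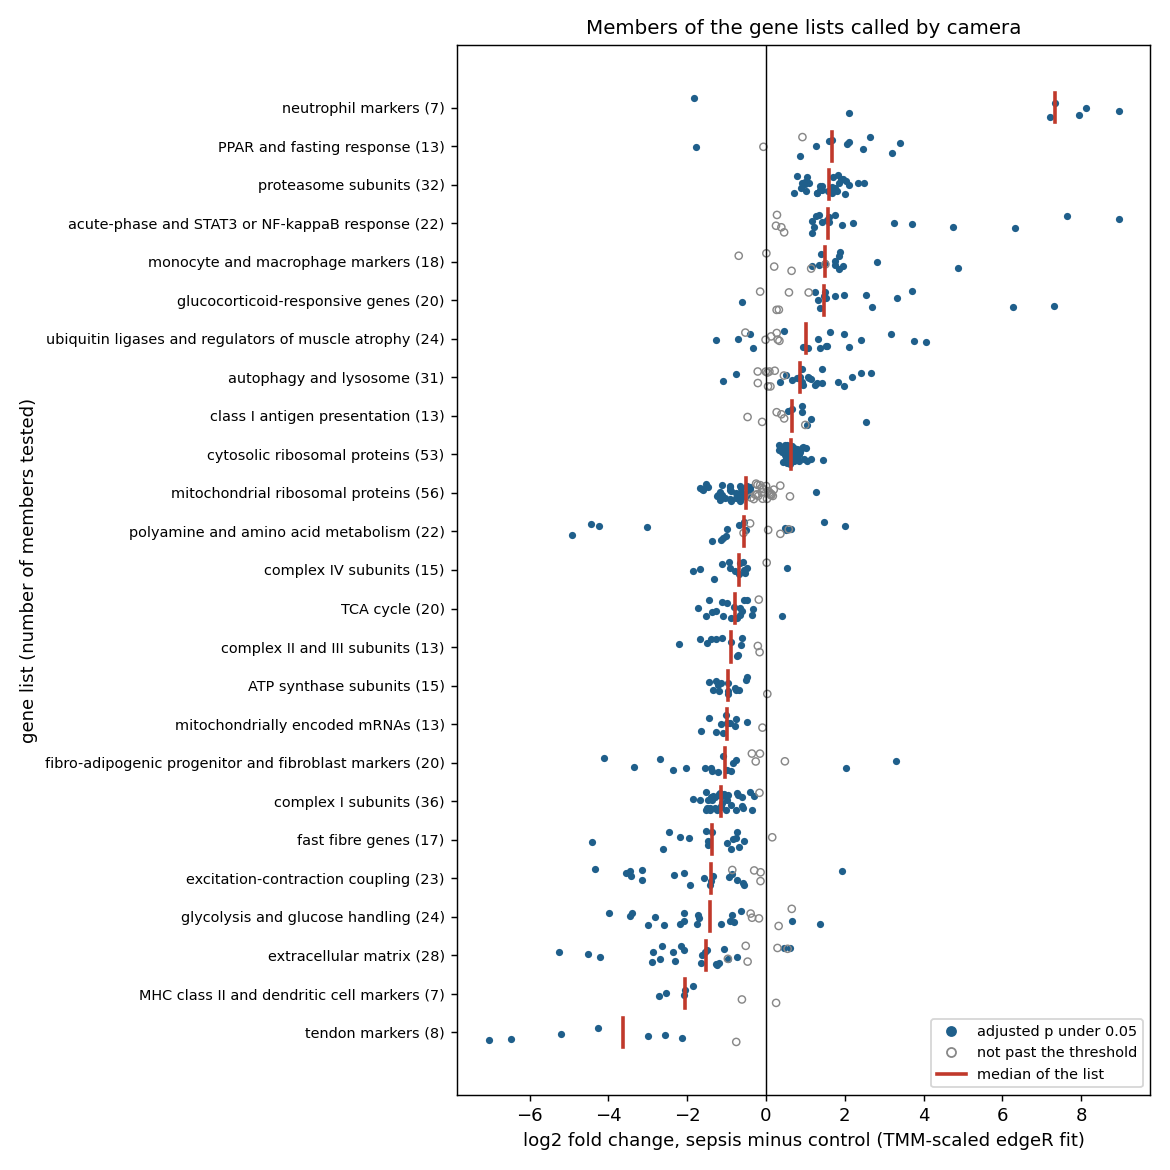
Log2 fold change (sepsis minus control) of each tested member of the 25 gene lists called by camera; filled points are past an adjusted p of 0.05, open points are not, and red lines are medians of fitted values. As scaled here all 32 proteasome genes lie right of 0 and all 36 complex I genes left of it; with library totals alone the points sit further right, and the mitochondrial ribosomal list is then 15 lower and 11 higher.

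Across the 47 lists with at least 5 tested members, camera called 25, of which 10 were higher and 15 lower. None held with an estimated correlation, where the lowest adjusted p was 0.31 and 4 lists had an unadjusted p below 0.05. Fry, which asks only whether the genes of a list move on balance in a single direction, called 40 lists, the 25 called by camera among them.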

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

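The tests chosen only after the results they measure were seen were those of room left in the libraries, of the TMM shift, of displaced fibre RNA, of fibroblasts, of tendon and of residual blood. The test of room left in the libraries was added because TMM lowers the proteasome and ribosomal folds, so that the planned comparison with library totals could hardly have gone against these increases. The tests of other splits, of TMM for the proteasome and ribosomal genes, of control 1 and of pan-leukocyte genes were fixed beforehand.

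Of the 56 splits of the 8 libraries into 5 and 3, 1 gave as many changed genes as the labels did, namely the labelled split itself. It gave 4943 changed genes and the highest other split gave 1. Being the highest of 56 splits is the most this test can show, and it does not exclude chance. Every other split mixes septic and control libraries in a group, which widens the spread within groups and holds its count down. A difference in handling that follows the groups is not excluded either.

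Proteasome and cytosolic ribosomal protein genes rose while complex I genes fell, in libraries whose most abundant transcripts took a smaller share in sepsis. With library totals alone the proteasome and ribosomal medians were 2.01 and 1.06, which decides little, since TMM lowers both. Room left by abundant transcripts would lift all genes alike by the median of 0.43. The lower quartiles of the 2 lists with library totals alone were 1.499 and 0.95, above that median. This comparison largely repeats the TMM-scaled result, in which every member of both lists was already higher, so it is no separate test. The complex I median stayed at -0.74 with library totals alone, which argues against the TMM shift as the whole of its fall. If all other cell types had displaced fibre RNA alike, their markers would rise together. They did not, as the upper quartile of the fibroblast markers was -0.33 and the lower quartile of the macrophage markers 1.15. This cannot decide whether leukocytes alone displaced fibre RNA, since that would lower fibroblast markers as well. Displacement alone would, however, lower all fibre transcripts alike. The 11 slow-fibre genes had a median of -0.24 with quartiles of -0.73 and 0.14, above the complex I quartiles of -1.37 and -0.76. The fast-fibre median was -1.36. For these genes the values argue against displacement as the whole of the complex I fall, and a smaller part stays open. A change in transcript levels within fibres may remain, as a hypothesis found and tested on the same data, and absolute RNA content was not measured.

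Fibrillar and type VI collagen genes fell, with a median of -2.88 over 8 genes. If fewer fibroblasts lowered all their markers as far, other markers would follow the collagens. The lower quartile of 10 fibroblast markers outside the matrix was -1.06, above the collagens' upper quartile of -2.67. Their upper quartile was 0.32, so some did not fall, while the full fibroblast list had a median of -1.04. A rise of some markers in sepsis could hide a loss of cells, so the comparison does not exclude fewer fibroblasts. All 8 collagens stayed lower past the threshold without control 1, which had the highest Fbn1 level. Less tendon in the septic samples remains open, because tendon markers had a median of -3.63, at least as low as the collagens. That median rests partly on Chad, Tnmd and Kera, which passed the expression filter through the controls only and could only come out lower. Without control 1 the tendon median was -2.72 over 7 markers tested, and no matching collagen median was computed. That test cannot separate less tendon tissue from lower transcription in tendon and matrix cells. The fall could therefore come from dissection as well as from sepsis.

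Neutrophil and macrophage markers rose. More residual blood would bring haemoglobin transcripts, but their summed level was 530 ± 435 CPM in controls and 59.0 ± 39.5 in sepsis, a log2 ratio of -3.17, with control 3 at 43.1 CPM within the septic range and p = 0.0893 in an exact permutation test of the log values. A change in the white or red cells of the remaining blood stays open, since haemoglobin transcripts do not measure blood volume. More leukocytes in the muscle is a hypothesis that the pan-leukocyte genes go with, since 7 of 10 tested rose with a median of 1.42. Infiltration and higher expression per cell were not separated.

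Single control libraries stood far from the other 4 in 13 of 166 values tested, or 7.83%, where chance gives about 1 in 20, and 6 of the 13 were in control 1. In control 1 the gap over the range was 1 for Itpkc, 0.768 for Uqcr11, 0.893 for Fbn1, 0.713 for Mki67, 0.742 for Cd74 and 0.71 for Tnmd. In control 3 it was 0.790 for Gpd1, 0.711 for Il6ra and 0.745 for Slc39a14. In control 5 it was 0.746 for Cox7a1 and 0.802 for Rora, in control 4 it was 0.766 for P4ha1, and in control 2 it was 0.743 for Oaz1. Of these, Fbn1 was at 68.6 CPM in control 1 and between 34.3 and 38.0 in the others, and Mki67 was at 3.89 CPM against 0.637 to 1.57.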

How the results depend on the processing

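All alternatives were planned before the data were examined. No gene called in edgeR's main comparison was called in the opposite direction by any of them. With library totals alone 4256 genes were higher and 1387 lower, and 78.1% of the called genes were shared. The cause was not tested. A log2 fold change of at least 1 left 2553 changed genes, 1157 higher and 1396 lower, by its own construction. The DESeq2 test called 4666 genes and limma-voom 4917. With each library left out, the changed genes ranged from 4428 to 5039, those higher from 2207 to 2533, those lower from 2221 to 2506, the lists called from 24 to 30, those higher from 9 to 13 and those lower from 14 to 17. Lists called with an estimated correlation numbered 0, with 0 higher and 0 lower, and fry called 40, with 19 higher. Of 156 named genes past the threshold, 145 stayed past it under every alternative other than the minimum fold, which 11 missed; Hbb-bt and Pf4 lost it most often, in 10 and 9 settings. Signs reversed only for values not past the threshold, and the cause was not tested. Nampt was at -0.025 with upper-quartile factors, -0.039 with limma-voom and -0.025 with the replicate block; left-out libraries gave -0.16 to 0.29, below 0 without control 2, sepsis 1 or sepsis 3. Myh7 was at 0.35 with library totals alone and -0.46 to 0.21 with a library left out, above 0 without control 3, control 4 or sepsis 3. Camera's direction, down in the main comparison, turned up for 3 lists it did not call. For the fatty acid and satellite cell lists it disagreed there with the mean shift against all other genes, which was already above 0 at 0.019 and 0.088; for the adipocyte list the shift was -0.13. The fatty acid list was at 0.042 with library totals alone and -0.14 to 0.16 with a library left out, with camera up without sepsis 2. The satellite cell list was at 0.27 with the stricter filter and -0.062 to 0.12 with a library left out, with camera up without sepsis 3. The adipocyte list ranged from -0.30 to 0.051, with camera up without sepsis 1. The replicate numbers share only a number: correlations of deviations between same-numbered libraries were -0.12, 0.04 and -0.02, and not every library correlated best with its own number. With the replicate block 3625 genes were called, 1741 higher and 1884 lower, the same number of lists, 25, and 6 named calls were lost, Myh4 and Rsad2 among them. The interferon list then had 0 members past the threshold. The extracellular matrix list had 0 higher and 19 lower, so the increases of Col4a1 and Col4a2 did not pass there. In simulations at this depth and these group sizes, with 200 of 9810 genes changed and 30 more raised, 1.5-fold changes were recovered in 15.2% of cases. In the real counts 50.4% of genes changed, so this recovery does not carry over to them. The share due to depth was not tested.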

Other observations

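The symbol families and the ratio of mitochondrial transcripts in this part were chosen after the data were seen. Of 146 families of genes sharing a symbol stem, the stem Eif, which covers translation initiation factors and some of their regulators, had 34 of 52 members higher, the repressor gene Eif4ebp1 among them, and 3, Eif4e, Eif4e3 and Eif4ebp2, lower. Its median was 0.58, and it included the helicase gene Eif4a1, up by 1.72, and Eif2s2, up by 1.19. DEAD-box RNA helicases (Ddx) had 19 of 32 higher and none lower, with the nucleolar helicase genes Ddx56 and Ddx18 at 2.02 and 1.47. RNA-binding motif genes (Rbm) had 13 of 31 higher and none lower, with the cold-inducible Rbm3 at 1.83. Membrane-scission genes of the ESCRT complex (Chmp) had 7 of 9 higher and none lower, with Chmp2b at 1.21. Complex I assembly factors (Ndufaf) had 7 of 8 lower, with Ndufaf5 at -2.41. Camera's adjusted p-values were 2.49e-05, 0.000529, 0.00671, 0.0283 and 0.00676, and each had an adjusted p = 0.74 with an estimated correlation.

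Stress and defence lists that camera did not call also held changed genes. Over all genes tested 50.4% changed, so a count of changed genes near that share does not set a list apart. The same background share applies to the other lists that camera did not call. Of 10 metallothionein and metal transport genes 5 rose, with the zinc importer gene Slc39a14 up 13.8-fold, and 2 fell, with the transferrin receptor gene Tfrc down 11.1-fold. Of 26 antioxidant genes 10 rose, among them Sod1, Gsr and Gclm, and 6 fell, or 10 and 7 adjusted over the list alone, while with library totals alone 14 were higher and 1 lower. Of 20 genes of the unfolded protein and integrated stress response 8 rose, with Atf4 up 2.25-fold, and 1 fell, or 2 without control 5 or sepsis 1. Of 17 heat shock protein genes 7 rose, with Hspb7 up 5.53-fold, and 0 fell, but 3 were lower without sepsis 3, and 1 without sepsis 1 or with upper-quartile factors. Their camera adjusted p-values were 0.116, 0.298, 0.143 and 0.101. The heat shock list passed without sepsis 2 at 0.0430, the lowest of its camera alternatives with the preset correlation, which reached 0.196.

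Growth, lipid and clock lists were mixed. Of 26 growth signalling genes 12 rose, among them Akt1, and 8 fell, among them Igf1, or 12 and 9 adjusted over the list alone, while with library totals alone 12 were higher and 4 lower and the median of 0.19 became 0.61. Of 19 lipid and sterol synthesis genes 9 fell, with Scd1 and Fasn down 6.12-fold and 3.81-fold, and 3 rose, and with library totals alone the median of -0.37 became 0.05, with 4 higher and 4 lower. With TMM scaling 1 was higher without sepsis 1, and the median was -0.71 without sepsis 3 and -0.59 without sepsis 2 or control 5. Of 18 clock genes 6 rose, with Cry2 up 5.87-fold and Rora 3.02-fold, and 2 fell (4 without control 3, 3 without control 2 or sepsis 1), while Dbp had -4.45 (SE 1.70) without passing. Of 11 cell cycle genes 5 rose, among them Hmgb2 and Mki67, and 1 fell, and without sepsis 1 there were 10 higher of 14 then tested, and without sepsis 2 there were 2 lower. Their camera adjusted p-values were 0.456, 0.108, 0.385 and 0.143. Without sepsis 1 the lipid list passed at 0.0370 and the cell cycle list at 0.0128, and the latter also passed with the stricter filter at 0.0202. Over the camera alternatives with the preset correlation the lipid and cell cycle lists reached 0.131 and 0.431.

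Markers of other cell types gave further values. Of 18 endothelial markers 9 rose, with Rgcc up 15.2-fold and P-selectin (Selp) 9.46-fold, and 4 fell, or 10 and 5 adjusted over the list alone, and 12 and 1 with library totals alone. Of 11 smooth muscle and pericyte markers 5 fell, with Acta2 down 2.19-fold, and with library totals alone the median of -0.38 became 0.03, with 2 higher and 2 lower. Of 8 Schwann cell markers 4 fell and none rose. Of 9 satellite cell markers 3 rose and 3 fell, with Vcam1 up 9.50-fold and Myod1 down 2.95-fold. Of 10 adipocyte markers 1, Plin4, rose and 1, Car3, fell, with 2 higher without sepsis 1 and 2 lower without control 5. Of 6 erythroid and platelet markers 1, Pf4, rose and 2, Bpgm and Hbb-bt, fell, with Bpgm down 10.1-fold and 3 lower adjusted over the list alone. The calls of Pf4 and Hbb-bt were each lost without 6 of the 8 single libraries, where the log2 fold changes were 0.63 to 1.23 for Pf4, against 1.13, and -5.52 to -3.50 for Hbb-bt, against -4.06, and 5 of the 6 markers were lower without control 3 and 3 without control 1, but 1 without any other library. Their camera adjusted p-values were 0.0966, 0.143, 0.0942, 0.961, 0.787 and 0.113; the endothelial list passed without sepsis 1 at 0.0381, the Schwann list with library totals alone at 0.0480, and the erythroid list with library totals alone at 0.0158 and without control 3 at 0.0254. Over the camera alternatives with the preset correlation these 3 lists reached 0.170, 0.193 and 0.233. The satellite list had a median of 0.07 and a mean of 0.12 and the adipocyte list a median of 0.09 and a mean of -0.12, while camera pointed down for both. With single libraries left out, the satellite median lay between -0.14 without sepsis 1 and 0.36 without sepsis 3, and was -0.10 without sepsis 2. The adipocyte median lay between -0.12 without sepsis 3 and 0.25 without sepsis 1, and was -0.03 without control 3. Of the lists too small for camera, 1 of 3 epidermal markers, Perp, rose 11.8-fold, with 1 lower without control 3 or sepsis 1, and the 1 liver gene tested, Cyp2e1, had 0.68 without passing, and passed at 1.19 without control 1 and at 1.10 with library totals alone.

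The log2 ratio of mt-Nd2 to mt-Co1 reads was 2.56 ± 0.0823 in controls and 0.99 ± 0.785 in sepsis, with p = 0.0179 in an exact permutation test, the smallest possible, and adjusted p = 0.0536. The share of Myh2 among adult myosin heavy chain reads was 2.68% ± 0.194 and 1.57% ± 1.13, with p = 0.0536 in the same exact test and adjusted p = 0.0964.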
